A study of Arabidopsis thaliana with 20 samples.

How the data were processed

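RNA was sequenced from inflorescences of Arabidopsis thaliana, the thale cress, in 5 groups of plants: the Columbia wild type, 2 lines that overexpress a DVL gene and 2 quintuple mutants. The DVL/RTFL (DEVIL/ROTUNDIFOLIA-LIKE) genes encode small plant peptides that alter organ shape when overexpressed. The overexpression lines were dvl1-1D, a dominant line with high DVL1, and 35S:DVL8, in which the 35S promoter of cauliflower mosaic virus drives DVL8. The dvl1 quintuple carried mutations in dvl1, dvl8, dvl11, rtfl11 and dvl19, and the rtfl9 quintuple in dvl8, dvl11, rtfl9, rtfl11 and dvl19, so the mutants shared 4 of their 5 mutated genes.

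Per the labels' protocols, total RNA was extracted with a silica column kit and DNase treatment on the column, and a sequencing company made the libraries and read them as pairs on an Illumina NovaSeq. The series text described whole inflorescences with the oldest flower at anthesis and independent biological replicates. The extraction protocol also named flowers after anthesis, and the source name inflorescence apices, so the exact mix of flower stages is uncertain. The series had 20 samples, 4 per group. The authors left out 5 of them, 1 per group, as outliers, and their criterion is not given in the sources used here. The other 15 libraries, 3 per group, were analysed here with the replicate numbers of the labels. Leaving out outliers can narrow the spread within groups and so lower p-values, which could not be checked here.

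The deposited values were RPKM per gene, reads scaled to gene length and to the total of the library,, computed by the authors. Cutadapt, HISAT2 and HTSeq are named in the submitters' processing notes, without versions, and the counting ignored strand, per the name of the deposited table. The genome build is not given in the sources used here. Of the 37336 gene identifiers in the table, 37051 were matched to the TAIR10.1 reference annotation, which gave names and coordinates, and 285 were not. Reads of a gene and an overlapping or antisense partner cannot be told apart without strand, so such genes were treated as uncertain, as were families of near-identical copies.

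Depth was recovered from the RPKM values, whose steps follow whole reads and gene length. Values came out as whole reads, within 0.005 of a read, for 29911 of the 29911 genes above 0 (100%), and 73.5% of the implied gene lengths equalled the exon union of the reference. The reads assigned to genes were between 22471893 and 36589877 per library. No pair of libraries of a group agreed within sampling noise: a chi-square statistic of their counts per gene, over genes with at least 20 reads, lay between 2.41 and 11.63, and all 15 libraries were kept as separate replicates. Intervals and floors computed from reads cover counting error only.

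Since the deposited unit was RPKM and not raw counts, the tests were limma (3.58.1, in R 4.3.3) with a mean-variance trend on log2(RPKM + 1), in a single fit of all 15 libraries with a mean per group. Genes with RPKM of at least 1 in at least 3 libraries were tested, 20223 in all. A fold change is on the log2(RPKM + 1) scale, which understates the change of genes at low RPKM. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05, and are two-sided. Against wild type, 4 comparisons were made, and 3 others compared dvl1-1D with 35S:DVL8, the dvl1 quintuple with the rtfl9 quintuple, and both overexpression lines with both quintuple mutants. A permutation test of a single gene in 3 against 3 libraries cannot go below 0.1. Where a group had 0 reads, a fold was computed against 3 reads over the whole group and given as a lower bound, and 95% intervals of ratios were from read counts.

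Before the data were examined, the groups, tests, alternatives and the rule for named genes were fixed, together with 24 gene lists. The lists were the DVL/RTFL family, TCP transcription factors, anthocyanin, auxin early response, brassinosteroid metabolism, carpel and fruit patterning, cell cycle, circadian clock, cytokinin response regulators, cytoskeleton and cell shape, expansins and wall loosening, floral organ identity, flowering time, gibberellin, heat shock, jasmonate, mature pollen, ovule and young seed, photosynthesis, rapid wound and touch response, salicylate and defence, shoot meristem and boundary, tapetum and exine, and trichome and epidermis. They held 388 members, of which 7 were dropped because their names could not be matched, and 322 of the other 381 passed the filter. Lists were compared with all other genes by camera with a preset correlation of 0.01, repeated with an estimated correlation, and adjusted over the 24 lists. The fry test asked whether the genes of a list moved, on balance, in a single direction, and its mixed form whether they changed in either direction; neither compares a list with other genes. Members were also adjusted over the list alone.

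Named genes were the genes of the labels and the 8 largest changes each way in a comparison with wild type. In a direct comparison the 5 largest each way were taken. These largest changes came from genes that passed the test and whose values did not overlap between the libraries of the groups compared. Of each list, up to 4 members that passed the test were named, by smallest adjusted p. Where fewer than 2 members of a list passed, the member with the smallest p was taken. Genes within 20 kb of DVL1 were also examined. Functional terms of the annotation with at least 10 tested and 8 called genes were added after seeing the data. Correlations between comparisons that share the wild-type libraries were set beside 100 simulations of unchanged groups. For genes called the same way in at least 3 lines, the mean of the 4 lines was also compared with wild type, with Bonferroni adjustment over all genes. The limma fit was tested on simulated data: with 20071 genes in dvl1-1D minus wild type, 92.5% of 67 genes changed 2-fold were recovered, and 3 of 174 calls were false (1.7%). Of 67 genes changed 1.5-fold, 68.7% were recovered. The simulated genes varied independently of each other, so the share of false calls need not hold for correlated genes. Apart from camera, the other tests were not run on these simulated data.

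Alternatives were a pseudocount of 0.1, no filter, a filter at RPKM 5, median-of-ratios scaling, quantile normalization, robust variance moderation, array quality weights, the replicate number as a block, a fit of only the groups compared, an estimated correlation for lists, a fold threshold of 1 on the log2 scale, and each library left out in turn. Chosen after seeing the data were voom, a limma method for read counts, on the recovered reads, and a fit without the pair of libraries farthest from their groups. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.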

Results

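Whole-genome expression was measured in inflorescences of Arabidopsis plants with raised or reduced activity of DVL/RTFL peptide genes. Wild-type Columbia, the overexpression lines dvl1-1D and 35S:DVL8, and the dvl1 and rtfl9 quintuple mutants were each represented by 3 independent biological replicates. Reads assigned to genes numbered 22752367, 28510627 and 33367920 in wild type and 23116154, 27080668 and 25836554 in dvl1-1D. They numbered 27869636, 27650371 and 33631436 in 35S:DVL8. The dvl1 quintuple libraries (replicates 2, 3 and 4) had 25327879, 27422680 and 36589877 reads, and the rtfl9 quintuple libraries (replicates 1, 2 and 4) 31603508, 27629337 and 22471893. Levels are RPKM as mean ± SD (n = 3), changes are log2 fold changes ± SE of log2(RPKM + 1), and adjusted p-values are from limma over 20223 genes. Along the leading principal component, which held 37.7% of the variance, the dvl1-1D libraries lay at 28.9 to 33.6 and all other libraries between -14.8 and -2.1. Replicate 2 of 35S:DVL8 and replicate 4 of the rtfl9 quintuple stood apart from their groups: 137 and 119 genes differed more than 2-fold there from both other replicates, against 19 to 74 genes in the remaining libraries.

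The genes named in the labels were examined first. DVL1 (AT5G16023, chromosome 5, 5232532 to 5233036, TAIR10.1) reached 559.7 ± 46.0 RPKM in dvl1-1D, with 21398 reads over the group. Wild type had 0 reads, so DVL1 was at least 7970-fold higher in dvl1-1D, computed against 3 reads over the wild-type libraries (9.13 ± 0.07, adjusted p = 2.85e-18). DVL1 also had 0 reads in 35S:DVL8 and the dvl1 quintuple, and 1 read in the rtfl9 quintuple. DVL8 (AT3G55515, chromosome 3, 20590263 to 20591401) reached 161.7 ± 10.9 RPKM in 35S:DVL8, with 16357 reads against 5 in wild type, a ratio of 3106 (95% counting interval 1330 to 9566; 7.27 ± 0.08, adjusted p = 5.19e-16). DVL8 had 10 reads in dvl1-1D, 2 in the dvl1 quintuple and 1 in the rtfl9 quintuple, and did not pass the test in any of these (log2 fold changes 0.08, -0.04 and -0.06). Each overexpression line thus showed the raised gene of its label in all 3 libraries, and not that of the other line.

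Loss of most mutated genes could not be checked from these levels, because they had few or no reads in wild type. DVL11 (AT2G39705, chromosome 2, 16556801 to 16558268) stood at 2.20 ± 0.398 RPKM in wild type, 2.49 ± 0.104 in dvl1-1D, 1.94 ± 0.482 in 35S:DVL8, 1.99 ± 0.216 in the dvl1 quintuple and 1.2 ± 0.235 in the rtfl9 quintuple. Its difference from wild type did not pass the test in any line, with the smallest adjusted p in the rtfl9 quintuple (-0.54 ± 0.13, adjusted p = 0.0599), where it did pass after median-of-ratios scaling or quantile normalization, with array weights, and without 35S:DVL8 replicate 2 and rtfl9 quintuple replicate 4. It was higher in both overexpression lines together than in both mutants together (0.32 ± 0.09, adjusted p = 0.0151), and kept that call with each of the 12 libraries left out in turn, but 35S:DVL8 and the dvl1 quintuple had similar levels. RTFL11 (AT1G17235, chromosome 1, 5895351 to 5896250) had 21 reads in wild type, 31 in dvl1-1D, 37 in 35S:DVL8 and 27 in each quintuple, and lay under the RPKM filter, so it was not tested. Loss of the transcripts of DVL11 (259 reads against 272 in wild type) and RTFL11 was thus not seen in the dvl1 quintuple, nor that of RTFL11 in the rtfl9 quintuple. RTFL9 (AT1G53708, chromosome 1, 20052393 to 20053195) and DVL19 (AT3G14362, chromosome 3, 4793678 to 4794417) had 0 reads in all libraries.

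**Figure D1:**
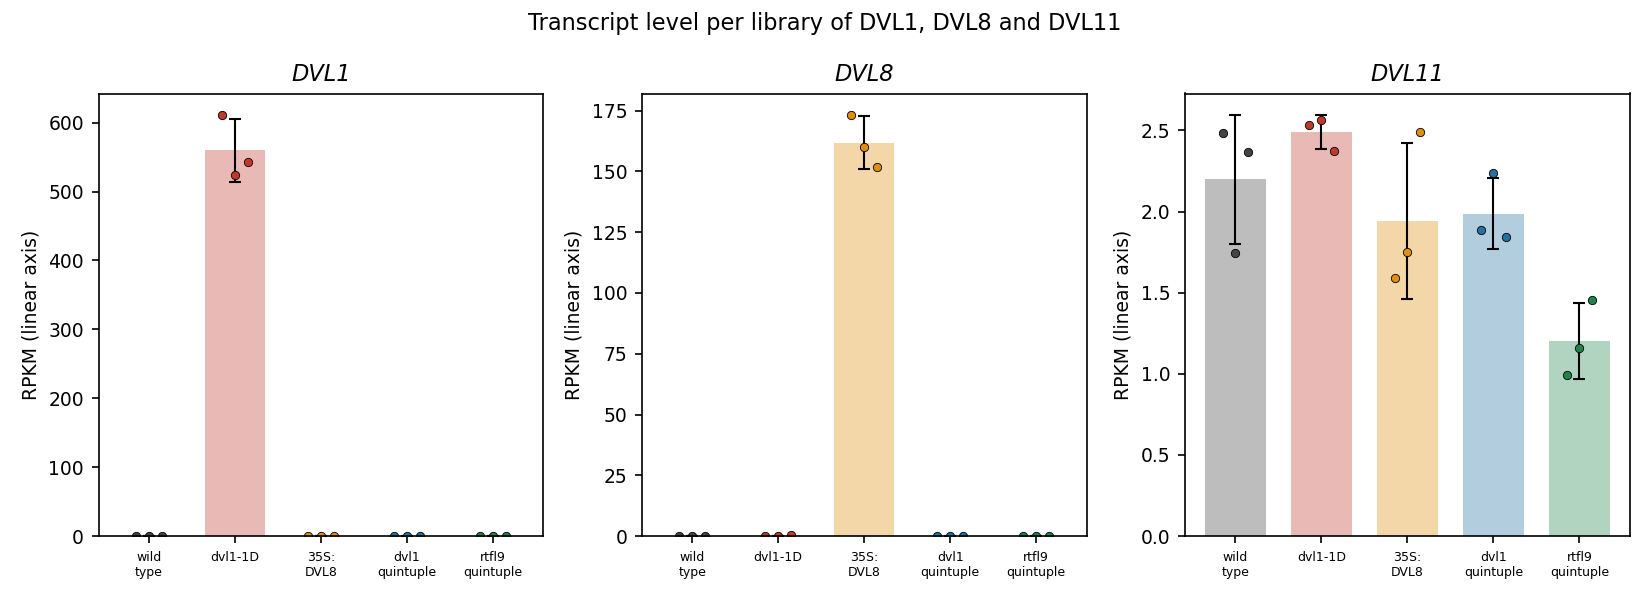
RPKM of DVL1, DVL8 and DVL11 (linear axes from 0) by group; bars are means, error bars the SD and points the 3 libraries of each group. DVL1 reached 559.7 RPKM in dvl1-1D alone and DVL8 161.7 RPKM in 35S:DVL8 alone, while DVL11 lay between 1.2 and 2.49 RPKM in all groups.

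The comparison of dvl1-1D with wild type asked which genes differ in the line with high DVL1. The largest increases after DVL1 were in genes of little known function and in the clock gene LHY. AT1G27565, an uncharacterized gene on chromosome 1 (9574550 to 9575189), rose from 0.0478 to 17.0 ± 2.04 RPKM (4.1 ± 0.11, adjusted p = 1.48e-11). The non-coding gene AT4G04223 rose from 3.98 ± 0.642 to 29.2 ± 3.89 RPKM (2.60 ± 0.13), AT5G21940 from 11.6 ± 0.511 to 47.9 ± 5.37 RPKM (1.95 ± 0.17), and AT4G27450, an aluminium-induced protein gene, from 5.08 to 21.2 ± 3.51 RPKM (1.85 ± 0.16). The pseudogene AT1G21525 (2.17 ± 0.26) and the uncharacterized AT1G19565 (2.08 ± 0.17) completed the largest increases, with adjusted p of 5.04e-05 and 4.38e-06. PCC1, a gene controlled by pathogens and the clock, fell from 58.2 ± 3.38 to 17.5 ± 5.96 RPKM (-1.73 ± 0.18, adjusted p = 2.37e-05), and the stress-tolerance gene AT3G22235 on the same chromosome from 81.9 ± 14.1 to 31.1 ± 6.15 RPKM (-1.37 ± 0.17). The non-coding AT2G05705 fell from 2.42 ± 0.0842 RPKM to 0 (-1.77 ± 0.18), and AT1G56300, a DnaJ chaperone gene, from 12.4 to 4.51 RPKM (-1.29 ± 0.15). Less certain decreases were in LpxC1 (-2.60 ± 0.80, adjusted p = 0.0249), which has close copies in the genome, in the tRNA gene AT2G33910 (-1.59 ± 0.45, adjusted p = 0.0159) and in the snoRNA gene AT5G07095 (-1.31 ± 0.34, adjusted p = 0.0106).

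In total 6219 of the 20223 genes (30.8%) differed between dvl1-1D and wild type. The counts of called members of each gene list in dvl1-1D are to be read against this share. Most changes were small, with a median absolute log2 fold change of 0.30 among the called genes, and 138 genes (113 higher, 25 lower) changed by at least 1. The higher calls numbered 3382 and the lower 2837 (54.4% higher), but only 43.9% were higher after median-of-ratios scaling and 44.3% after quantile normalization, so the balance of directions depended on scaling. In 47% of genes the libraries of both groups did not overlap, against 10% given by chance. The 10% is the share for libraries assigned to groups at random. It is not a firm bound, here or in the other comparisons, since genes vary together and samples had been left out as outliers.

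Clock genes moved in both directions. LHY and CCA1, MYB genes expressed at dawn, rose in dvl1-1D, LHY from 10.5 ± 0.330 to 41.9 ± 3.24 RPKM (1.89 ± 0.21, adjusted p = 2.92e-05) and CCA1 by 0.25 (adjusted p = 0.00358). RVE8, a related MYB gene, rose from 10.8 ± 0.989 to 18.3 ± 1.82 RPKM (0.71, adjusted p = 0.000145). Lower were 6 genes, among them PRR5, a repressor of CCA1 and LHY, which fell from 19.1 ± 1.39 to 6.81 ± 0.168 RPKM (-1.36 ± 0.16, adjusted p = 5.59e-05). The RNA-binding protein gene CCR2 fell from 536.3 ± 9.23 to 248.6 ± 10.6 RPKM (-1.11 ± 0.08, adjusted p = 2.77e-06), and GI (-0.41), ELF3 (-0.38), ELF4 (-0.62) and PRR7 (-0.21) were lower too. Of the 12 tested clock genes, 3 were higher and 6 lower, also when adjusted over the list alone. By fry the list moved downward on balance (adjusted p = 0.000536), but it did not pass by camera (adjusted p = 0.12, or 0.324 with an estimated correlation). Camera looks for a shift in a single direction. It therefore cannot tell whether a list whose members moved both ways stood apart from other genes.

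Brassinosteroid genes were mostly higher in dvl1-1D: 6 of 11 rose and 1 fell, with the same counts adjusted over the list alone. BR6OX2, an oxidase of the last steps of brassinolide synthesis, rose from 19.8 ± 0.280 to 40.4 ± 4.90 RPKM (0.98 ± 0.07, adjusted p = 1.26e-06). The cytochrome P450 genes BR6OX1 (0.47), CPD (0.35 ± 0.07), DWF4 (0.29) and ROT3 (0.28) and the desaturase gene DWF7 (0.15) rose as well, while DET2, a steroid reductase, fell (-0.45 ± 0.06, adjusted p = 9.49e-05). The fry adjusted p was 4.52e-05 and the camera adjusted p 0.12. Of 13 genes of rapid wound and touch responses, 5 rose and 0 fell by limma (6 and 1 at an unadjusted p under 0.05), and 6 rose when adjusted over the list alone (camera adjusted p = 0.12; 0.931 with an estimated correlation). MYB51, a regulator of indole glucosinolates, rose from 0.819 to 4.34 ± 1.32 RPKM (1.52 ± 0.20, adjusted p = 0.000114), and TCH3, a calmodulin-like touch gene, from 5.64 to 17.5 ± 4.20 RPKM (1.46 ± 0.21, adjusted p = 0.000187). The others were WRKY46 (1.03 ± 0.29), ERF6 (0.59) and WRKY33 (0.48).

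Of 20 cell cycle genes 8 fell in dvl1-1D and 1, the CDK inhibitor gene KRP2, rose (0.33, adjusted p = 0.0136), with the same counts adjusted over the list alone. CDKB2;1, a kinase of mitosis, fell from 36.3 to 28.7 RPKM (-0.33 ± 0.05, adjusted p = 0.000262), and so did the B-type cyclin CYCB1;4 (-0.34), the helicase subunit MCM2 (-0.21) and the kinase AUR2 (-0.28). This was the single list called by camera in dvl1-1D (down, adjusted p = 0.005, or 0.876 with an estimated correlation), and the means of its members lay at -0.17, -0.15 and -0.16 in the 3 dvl1-1D libraries relative to wild type. Among 10 splits of the dvl1-1D and wild-type libraries, 9 gave at least 1 list called by camera, the real one included. Of 13 meristem and boundary genes 4 rose and 0 fell by limma (4 and 1 at an unadjusted p under 0.05), also adjusted over the list alone (fry adjusted p = 0.027; camera adjusted p = 0.41; 0.931 with an estimated correlation). They were the homeobox genes STM (46.6 to 57.9 RPKM, 0.31 ± 0.05, adjusted p = 0.000393), KNAT6 (0.28) and KNAT2 (0.28) and the receptor kinase CLV1 (0.26); after quantile normalization 2 rose and 1 fell.

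TCP transcription factors, regulators of organ growth, moved in both directions: 8 of 17 rose and 3 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.576). TCP4, which limits cell proliferation in leaves and petals, fell from 16.3 to 9.50 RPKM (-0.72 ± 0.11, adjusted p = 0.000344), with TCP1 (-0.71 ± 0.13) and TCP2 (-0.41), whereas TCP15 rose from 45.0 to 54.2 RPKM (0.26 ± 0.05, adjusted p = 0.00152). Of 16 expansin and wall-loosening genes 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.15, fry adjusted p = 0.044), and 1 rose and 5 fell after median-of-ratios scaling. EXPA15 fell from 76.2 ± 4.17 to 36.7 ± 2.68 RPKM (-1.04 ± 0.08, adjusted p = 2.35e-06), with EXPA10 (-0.49) and EXPB3 (-0.39), and the xyloglucan-modifying touch gene TCH4 rose from 3.54 to 9.61 ± 1.99 RPKM (1.21 ± 0.27, adjusted p = 0.00416). Of 16 cytoskeleton and cell shape genes 4 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.494), including LNG2, which promotes organ elongation (0.52 ± 0.06, adjusted p = 4.91e-05), LNG1 (0.18), the GTPase gene ROP2 (0.20) and, lower, the exchange factor SPK1 (-0.40 ± 0.04, adjusted p = 1.58e-05). Of 11 trichome and epidermis genes 1 rose, GL2 (0.50), and 4 fell, among them MYB16 (-0.45 ± 0.05), TRY (-0.49) and EGL3 (-0.36), with the same counts adjusted over the list alone (fry adjusted p = 0.0186; camera adjusted p = 0.469).

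**Figure D2:**
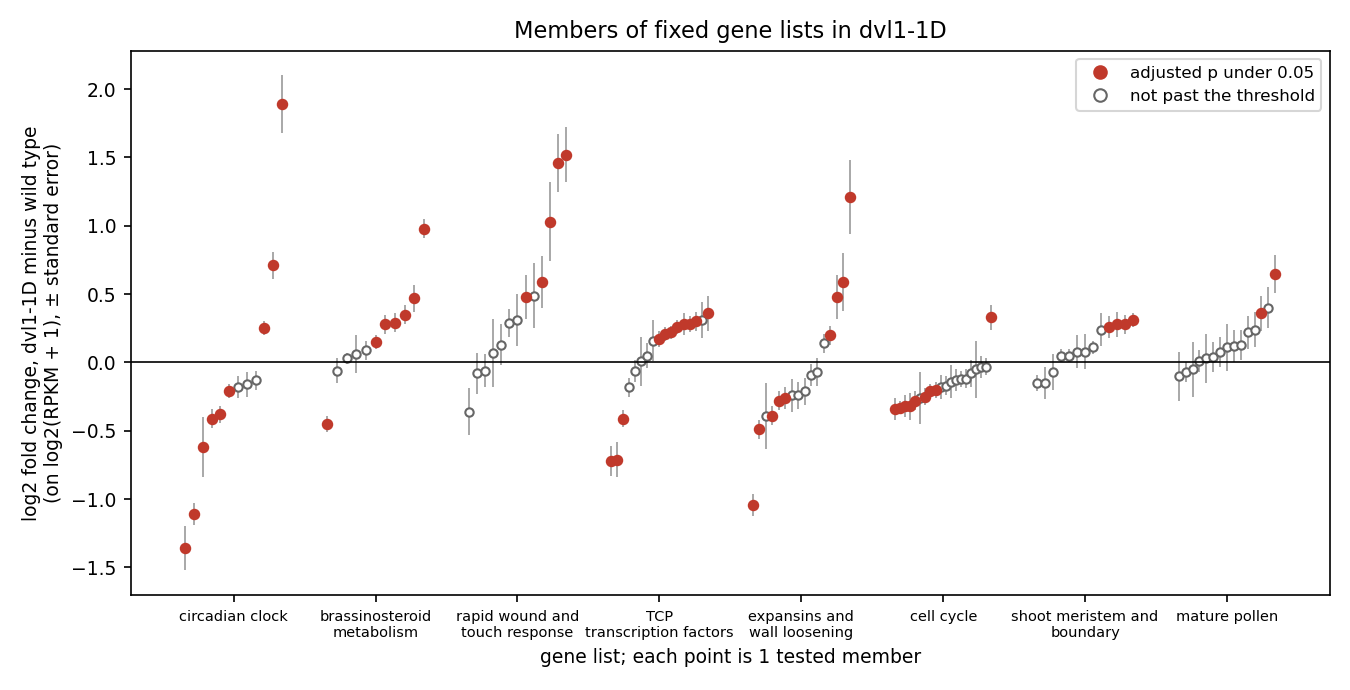
Log2 fold change of log2(RPKM + 1), dvl1-1D minus wild type, of each tested member of 8 gene lists; points are estimates with their SE, filled red where the adjusted p was under 0.05. Clock genes lay on both sides of 0, from 1.89 for LHY to -1.36 for PRR5, and 8 of the 20 cell cycle genes were called lower.

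Hormone and developmental lists gave mixed results in dvl1-1D. Adjusted over the list alone, the counts were those given here unless stated. Of 16 early auxin genes 6 rose and 3 fell, among them IAA2 (0.42), GH3.5 (0.48) and IAA14 (0.51) higher and IAA5 lower (-0.65); the list's median was -0.04, its mean 0.03 and its camera direction up (adjusted p = 0.832). Of 13 gibberellin genes 1 rose, GASA4 (0.26), and 4 fell, including RGL2 (-0.50), GA2OX1 (-0.52) and GA20OX1 (-0.49), with a median of 0.13, a mean of -0.06 and a camera direction of down (adjusted p = 0.711). AOC3 (0.67) rose and OPR3 (-0.42) and VSP2 (-0.55) fell among 18 jasmonate genes (camera adjusted p = 0.576), and ARR9 (0.36) alone rose among 9 cytokinin response regulators (adjusted p = 0.757), where 0 fell by limma and 2 rose at an unadjusted p under 0.05. Of 12 salicylate and defence genes 4 rose and 2 fell, or 5 and 2 adjusted over the list alone, with NIMIN1, an inhibitor of NPR1 signalling, falling from 25.3 to 11.3 RPKM (-1.11 ± 0.12, adjusted p = 3.26e-05), PBS3 lower (-0.41), and EDS1 (0.53) and WRKY53 (0.57) higher (camera adjusted p = 0.607).

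In flower-related lists, with the counts adjusted over the list alone again the same unless stated, AG, which specifies stamens and carpels, rose (0.37, adjusted p = 0.00043) and AGL6 (-0.39) and CAL (-0.38) fell among 14 floral identity genes (camera adjusted p = 0.832). FLC, a repressor of flowering, rose from 0.186 to 1.37 RPKM (1.00 ± 0.11, adjusted p = 4.3e-05), FD rose (0.59), and SPL9 (-0.32), MAF1 (-0.31) and 1 other gene fell among 12 flowering-time genes (adjusted p = 0.832). Of 19 carpel and fruit genes 3 rose and 2 fell, CRC, needed for nectaries and carpels, rising by 0.57 ± 0.08 (adjusted p = 0.000256), NGA4 by 0.45, and YAB3 (-0.37) and YAB1 (-0.33) falling (camera adjusted p = 0.832). Of 8 ovule genes 1 fell and 0 rose by limma, with 2 each way at an unadjusted p under 0.05; their median was 0.01, their mean 0.08 and the camera direction down (adjusted p = 0.832). Of 15 pollen genes TIP1;3 (0.65 ± 0.14) and PPME1 (0.36) rose, 1 of them adjusted over the list alone, and 0 fell by limma or at an unadjusted p under 0.05 (camera adjusted p = 0.523). Of 13 tapetum genes 1 rose, GRP17, a pollen-coat protein gene (454.9 ± 42.2 to 767.8 ± 83.6 RPKM, 0.75 ± 0.10, adjusted p = 0.00015), with 0 lower at either threshold, a median of -0.08, a mean of 0 and a camera direction of down (adjusted p = 0.848). UF3GT (0.59) rose and CHI (-0.21), F3'H (-0.32) and TT4 (-0.16) fell among 9 anthocyanin genes, whose median of 0.28 and mean of 0.22 were positive while the camera direction was down (adjusted p = 0.848). Of 18 photosynthesis genes RBCS1B fell (-0.54) and LHCB2.1 rose (0.24), which was 1 lower and 0 higher adjusted over the list alone, with a median of 0.02, a mean of -0.01 and a camera direction of down (adjusted p = 0.848). Of 5 heat shock genes 0 passed limma's test and 0 had an unadjusted p under 0.05, the smallest p being that of ROF2 (0.17, adjusted p = 0.187; camera adjusted p = 0.923). The camera directions of the anthocyanin and tapetum lists were up after quantile normalization.

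Within the DVL/RTFL family, DVL6 rose from 23.3 to 36.6 RPKM in dvl1-1D (0.64 ± 0.05, adjusted p = 2.77e-06) and ROT4 from 2.68 to 6.70 ± 3.12 RPKM (0.99 ± 0.22, adjusted p = 0.00358). DVL4 (0.42) and DVL17 (0.34) were higher and DVL18 (-0.28) lower, so that, with DVL1, 5 of 12 rose and 1 fell (5 and 2 adjusted over the list alone). The list includes DVL1 itself, so its list tests say little about the other members. By camera the family did not pass (adjusted p = 0.0654; 0.324 with an estimated correlation), but it did after median-of-ratios scaling (0.0258) and quantile normalization (0.0447). Of 11 tested genes within 20 kb of DVL1, 6 differed, where 30.8% of all tested genes did. AT5G16030, the next protein-coding gene towards higher coordinates, rose from 16.1 to 39.3 ± 4.38 RPKM (1.24 ± 0.07, adjusted p = 7.05e-07), and NIK1 (0.54 ± 0.05), AT5G16010 (0.68) and GEX3 (0.66) rose too. The non-coding AT5G02515 (0.94) overlaps AT5G16030, so its reads are uncertain, and AT5G15980 was lower (-0.31).

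By fry 7 of the 24 lists, the family with DVL1 among them, moved, on balance, a single way in dvl1-1D, and 19 changed in either direction, while with an estimated correlation 0 were called by camera (smallest adjusted p = 0.324). With 30.8% of all tested genes called, a fry result does not set a list apart from other genes. Some named calls were lost when a library was left out, which also leaves fewer samples. Without dvl1-1D replicate 1, AT2G33910, EDS1, GASA4, KNAT2, KNAT6, LHCB2.1, LNG1, TT4, WRKY46 and WRKY53 lost the call (adjusted p between 0.0511 and 0.146), with KNAT2 at 0.18. Without replicate 2, CLV1, ERF6, LpxC1 and PPME1 did (0.0662 to 0.22), with PPME1 at 0.20, and without replicate 3, AT2G33910, CLV1, ERF6, FD, LHCB2.1 and LpxC1 (0.0501 to 0.117). Without wild-type replicate 1, CLV1, ERF6, LHCB2.1, LpxC1 and PPME1 lost it (0.0663 to 0.157), without replicate 2, AT2G33910, CLV1, ERF6, GASA4, KNAT2, LpxC1, PPME1, TT4, WRKY46 and WRKY53 (0.0519 to 0.11), and without replicate 3, CLV1, FD, KNAT2, LHCB2.1, LNG1 and PPME1 (0.0652 to 0.0918).

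The comparison of 35S:DVL8 with wild type asked the same of the line with high DVL8. Apart from DVL8, the largest change was a decrease of AT5G45280, a pectin acetylesterase gene on chromosome 5 (18345534 to 18349695), from 20.9 ± 1.78 to 0.793 ± 0.0172 RPKM (-3.60 ± 0.08, adjusted p = 1.35e-12). HEI10, which promotes meiotic crossovers, fell from 3.01 to 1.13 RPKM (-0.90 ± 0.10, adjusted p = 0.00135), and GH9B11, a glycosyl hydrolase gene, from 8.50 to 4.30 RPKM (-0.86 ± 0.12, adjusted p = 0.0102). The cupin gene AT1G74820 rose from 0.828 to 3.76 ± 0.467 RPKM (1.38 ± 0.18, adjusted p = 0.00706), SWEET9, the sucrose exporter of nectaries, from 39.2 ± 0.782 to 62.1 ± 11.1 RPKM (0.63 ± 0.11, adjusted p = 0.0393), and FSD1, an iron superoxide dismutase gene, from 311.4 ± 41.0 to 481.7 ± 35.5 RPKM (0.63 ± 0.10, adjusted p = 0.0267). The other named increases were the non-coding AT3G06645 (1.17) and AT3G29644 (0.59), the pseudogene RLP18 (0.77) and AT2G34655 (0.60). The other named decreases were the pseudogene AT3G42090 (-1.50), the non-coding AT2G05705 (-1.43), the lipase-like AT2G19050 (-0.89), the zinc finger gene AT2G40990 (-0.76) and AT2G13350 (-0.69).

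In all, 28 genes differed in 35S:DVL8, 12 higher and 16 lower, and 2125 had an unadjusted p under 0.05. In 16.4% of genes the libraries of both groups did not overlap, against 10% given by chance. The balance of directions varied, with 54 higher and 233 lower of 287 genes without 35S:DVL8 replicate 1, 74 and 232 with array weights, and 48 and 193 with voom. The count was 4 without replicate 3, and 6, 8 and 8 without wild-type replicates 1, 2 and 3. DVL8, AT5G45280, HEI10, AT3G06645 and AT3G29644 kept their call in every fit without a single library in which they were tested. AT2G05705 lost it without 35S:DVL8 replicate 3 (adjusted p = 0.0619). The other 10 named genes lost it without that library too (up to 0.112), and some of them lost it without 35S:DVL8 replicate 2 (0.0712 to 0.0992: AT2G19050, AT2G40990, AT3G42090 and RLP18). Without wild-type replicate 1 all 10 lost it (0.0788 to 0.142), without replicate 2 all of them except FSD1 (0.0553 to 0.193), and without replicate 3 all except AT1G74820 (0.0557 to 0.175).

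Pollen genes were lower in 35S:DVL8. Among 15 of them 0 passed limma's test over all genes, but 9 were lower at an unadjusted p under 0.05 and the same number adjusted over the list alone. The list's median was -0.31 (camera adjusted p = 1.58e-06; 0.355 with an estimated correlation; fry adjusted p = 0.127, mixed 0.00936), and its means in the 3 libraries were -0.24, -0.55 and -0.16 relative to wild type. Its smallest p was that of TIP5;1, an aquaporin gene of pollen (6.85 to 4.27 RPKM, -0.58 ± 0.11, adjusted p = 0.0596). Among 10 splits of the 35S:DVL8 and wild-type libraries, 2 reached the real count of 7 lists called by camera, the real one included.

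Other lists called by camera in 35S:DVL8 did not pass with some libraries left out. Salicylate and defence genes were higher (median 0.38, adjusted p = 0.000117; 0.595 with an estimated correlation), with means of -0.01, 1.09 and 0.28 in the 3 libraries and an adjusted p of 0.24 without replicate 2, the library that stood apart. PR2, a defence glucanase gene, stood at 44.9 ± 46.8 RPKM against 10.1 ± 2.97 (1.58 ± 0.58, adjusted p = 0.31). Wound and touch genes were higher (0.0168; 0.604 with an estimated correlation), with means of -0.09, 0.41 and 0.30, and did not pass without replicate 2 (0.231) or 3 (0.0764). Trichome genes were lower (0.017; 0.278 with an estimated correlation; fry adjusted p = 0.039) and did not pass without replicate 2 (0.071) or 3 (0.0764). Anthocyanin genes were lower (0.0225; 0.604 with an estimated correlation), and did not pass without replicate 2 (0.0773) or 3 (0.259) or wild-type replicate 2 (0.0527). Photosynthesis genes were higher (0.0475; 0.878 with an estimated correlation), and did not pass without replicate 1 (0.804), replicate 2 (0.373) or wild-type replicate 1 (0.908), nor after median-of-ratios scaling (0.0686) or quantile normalization (0.469). The DVL/RTFL family (0.0272; 0.278 with an estimated correlation) held by DVL8 alone, and did not pass without replicates 1, 2 or 3 (0.891, 0.452 and 0.831), where DVL8 fell under the filter.

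In these 7 lists DVL8 alone passed limma's test over all genes, and over all 24 lists 1 member was called and 60 had an unadjusted p under 0.05. Adjusted over the list alone, 0 salicylate, wound, trichome and photosynthesis genes passed by limma (4, 3, 3 and 0 at an unadjusted p under 0.05), 1 anthocyanin gene was lower, 3 TCP genes were higher and 2 lower (fry mixed adjusted p = 3.85e-06), 3 carpel genes were higher and 3 lower (1.43e-05), 1 tapetum gene was higher, and 1 gene each of the cytoskeleton, gibberellin and ovule lists was lower. Members with the smallest p included TCP1 (-0.65, adjusted p = 0.065), GA2OX1 (-0.44, 0.0702), RIC1 (-0.68, 0.133), TCH2 (0.36, 0.154), GRP17 (0.36, 0.154), YAB3 (-0.25, 0.177), AP1 (-0.23, 0.216), MYB16 (-0.16, 0.247) and PRR7 (0.08, 0.677).

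The comparison of the dvl1 quintuple with wild type asked which genes respond to mutation of DVL1, DVL8, DVL11, RTFL11 and DVL19. It gave 6 genes, 4 higher and 2 lower, and 4 of them were non-coding genes or pseudogenes. A fit of only the groups compared gave 161 genes (14 higher, 147 lower). A fit without 35S:DVL8 replicate 2 and rtfl9 quintuple replicate 4, chosen after seeing the data, gave 152 (11 higher, 141 lower). The pseudogene AT5G35935 (chromosome 5, 14083388 to 14089891) rose from 0.0137 to 4.90 ± 0.323 RPKM (2.54 ± 0.09, adjusted p = 2e-09). The non-coding AT3G06355 rose from 9.24 to 20.5 RPKM (1.07 ± 0.12, adjusted p = 0.00279) and AT3G29644 from 1.62 to 3.96 RPKM (0.92, adjusted p = 2.36e-05), and the uncharacterized AT2G13550 rose by 0.89 ± 0.12 (adjusted p = 0.0138). HEI10 fell from 3.01 ± 0.448 to 1.19 ± 0.0138 RPKM (-0.87 ± 0.10, adjusted p = 0.00279), and AT2G05705 fell as well (-1.37, adjusted p = 0.00974). At an unadjusted p under 0.05 there were 1568 genes, and in 16.5% of genes the libraries of both groups did not overlap, against 10% by chance. AT2G13550 lost the call without dvl1 quintuple replicates 2 (0.105) or 4 (0.0623) and without wild-type replicates 1, 2 or 3 (0.155, 0.0766 and 0.118), and AT2G05705 without dvl1 quintuple replicate 4 (0.0516). The count was 4 without that replicate or any wild-type library.

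By camera with the preset correlation, tapetum genes were higher and pollen genes lower in the dvl1 quintuple. By fry 0 lists moved a single way and 0 changed in either direction. Of the 10 splits of these libraries into 3 against 3, 6 reached the real count of 3 called lists, the real split among them. The tapetum list had a median of 0.39 (camera adjusted p = 7.4e-05; 0.926 with an estimated correlation) and means of 0.30, 0.33 and 0.41 in the 3 libraries, although 0 of its 13 members passed limma's test, adjusted over the list alone or over all genes, and 4 were higher at an unadjusted p under 0.05. CYP704B1, which makes sporopollenin precursors, had the smallest p (0.46, adjusted p = 0.472). The pollen list had a median of -0.17 (camera adjusted p = 0.00012; 0.926 with an estimated correlation), means of -0.26, -0.11 and -0.25, and 6 of 15 members lower adjusted over the list alone, the smallest p being that of ROPGEF12 (-0.56, adjusted p = 0.449). Wound and touch genes were higher (0.0284; 0.926 with an estimated correlation), with means of 0.22, 0.50 and -0.09, but not without dvl1 quintuple replicates 2 (0.0623) or 3 (0.864) or wild-type replicates 2 (0.0524) or 3 (0.0529). By limma 0 members of the 24 lists were called, against 23 at an unadjusted p under 0.05. Cell cycle genes, whose camera adjusted p was 0.0613, passed after median-of-ratios scaling (up, 0.0385).

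The rtfl9 quintuple, which is mutated in RTFL9 in place of DVL1, differed from wild type in 249 genes, 65 higher and 184 lower, but without a filter in 57, 30 higher and 27 lower. AT5G35935 rose to 5.23 RPKM (2.62, adjusted p = 1.3e-09), and AT4G04223 (1.34), AT3G06355 (1.26), AT2G13550 (1.09), AT3G29633 (1.02), AT3G29644 (0.98) and the pseudogene AT3G30122 (1.09) rose too. AT5G37940, a zinc-binding dehydrogenase gene, rose from 17.3 to 38.4 RPKM (1.11 ± 0.17, adjusted p = 0.0168). Among the lower genes, the pectin methylesterase inhibitor gene APPB1 fell from 46.7 to 22.9 RPKM (-1.0 ± 0.19, adjusted p = 0.0294), the glycosyl hydrolase gene AT5G20390 from 22.7 to 10.2 RPKM (-1.09 ± 0.20, adjusted p = 0.0289), and the leucine-rich repeat genes AT4G33970 (18.1 to 8.41 RPKM, -1.03) and AT2G15880 (-0.99) fell with them. RALFL26, which encodes a secreted peptide, fell from 26.9 to 13.1 RPKM (-0.98 ± 0.22, adjusted p = 0.0452), and ANX2, a receptor kinase that keeps pollen tubes intact, from 10.2 to 5.47 RPKM (-0.78 ± 0.18, adjusted p = 0.0493). AT2G05705 (-1.66), AT3G42090 (2.35 RPKM to 0, -1.74), AT1G68110 (-0.98) and HEI10 (-0.74, adjusted p = 0.0064) were lower too.

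At an unadjusted p under 0.05 there were 3189 genes, and in 21.1% of genes the libraries did not overlap, against 10% by chance. The count of 249 fell to 13, 79 and 23 without rtfl9 quintuple replicates 1, 2 and 4, and to 9, 8 and 7 without wild-type replicates 1, 2 and 3. The excess of lower genes did not hold in all of these fits: 9 were higher and 4 lower without mutant replicate 1, 13 and 10 without replicate 4, and 9, 7 and 7 were higher without the wild-type libraries. AT5G35935, AT4G04223, AT3G06355, AT3G30122, AT2G13550, AT3G29633 and AT3G29644 kept their call in each of these fits, and AT2G05705 in the 3 in which it was tested, those without a mutant library. ANX2, APPB1, AT1G68110, AT2G15880 and RALFL26 lost it in each. AT4G33970 and AT5G20390 lost it in each except without replicate 2 of the mutant, and AT3G42090 and AT5G37940 without replicate 1 and each wild-type library. The highest adjusted p of these lost calls was 0.117, 0.087 and 0.145 without mutant replicates 1, 2 and 4, and 0.0848, 0.223 and 0.172 without wild-type replicates 1, 2 and 3.

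Pollen genes were lower in the rtfl9 quintuple as well: 8 of 15 adjusted over the list alone, 1 over all genes, with a median of -0.34 (camera adjusted p = 2.41e-05; 0.961 with an estimated correlation) and means of -0.37, -0.28 and -0.25 in the 3 libraries. Tapetum genes were higher (median 0.42, camera adjusted p = 0.000346; 0.961 with an estimated correlation), with means of 0.10 and 0.28 in replicates 1 and 2 and 0.81 in replicate 4, the library that stood apart; 0 members passed limma's test adjusted over the list alone and 6 were higher at an unadjusted p under 0.05. MS2, a gene of exine formation, had the smallest p (0.56, adjusted p = 0.169). Cell cycle genes were higher (median 0.13, camera adjusted p = 0.00637; 0.961 with an estimated correlation), with 0 called by limma, 7 higher at an unadjusted p under 0.05 and CYCD3;1 first (0.17, adjusted p = 0.193), but did not pass without replicate 1 (0.0523) or wild-type replicate 2 (0.0907). Among 10 splits of the rtfl9 quintuple and wild-type libraries, 6 reached the real count of 3 lists called by camera, the real one included. By fry 0 lists moved a single way, and 3 changed in either direction: the DVL/RTFL family, brassinosteroid genes and pollen genes. Adjusted over the list alone, 1 family member was higher and 2 lower, 1 TCP, 1 brassinosteroid and 1 ovule gene were higher, 1 carpel gene was lower, and cytoskeleton genes had 1 each way. Other members with the smallest p of their list were TCP21 (0.31, adjusted p = 0.0815), IND (-0.50, 0.067), RIC1 (-0.68, 0.102), ANT (0.21, 0.111), WRKY70 (0.59, 0.16) and LFY (0.43, 0.219).

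**Figure D3:**
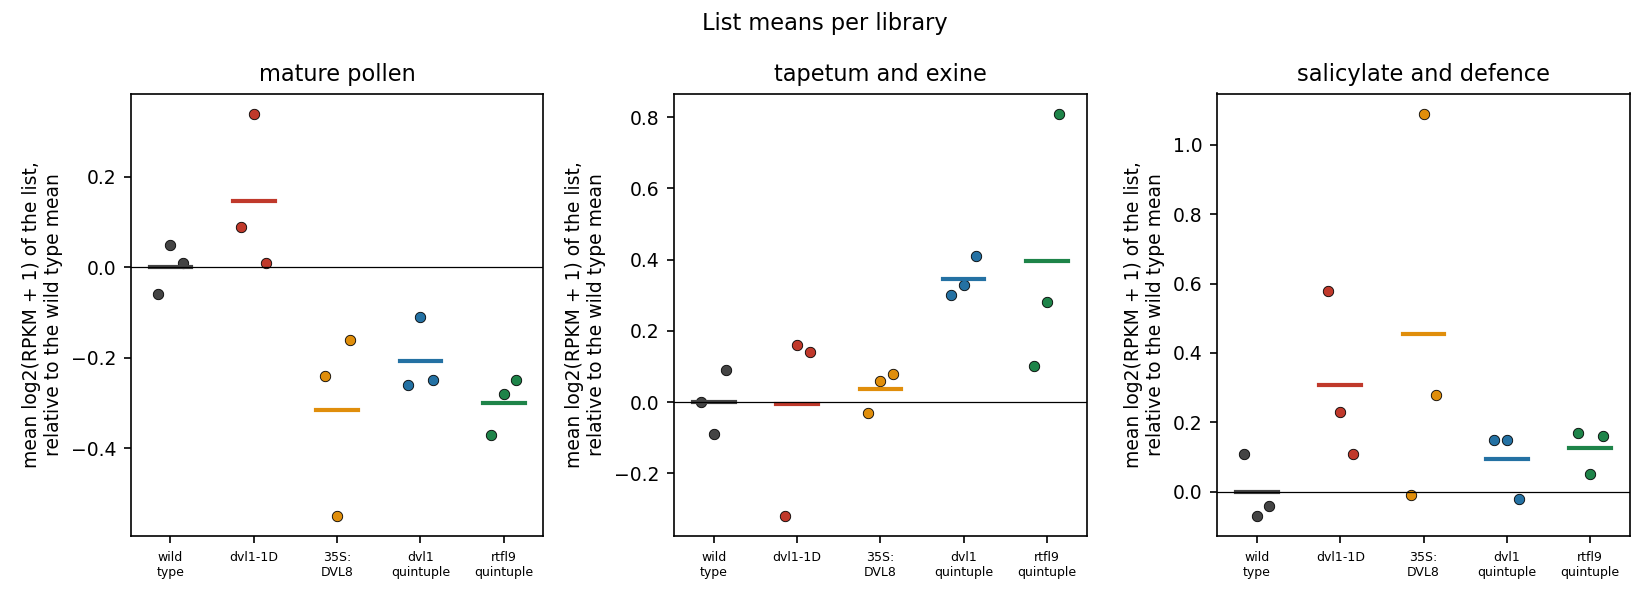
Mean log2(RPKM + 1) of the pollen, tapetum and salicylate lists in each library (points), relative to the wild-type mean; lines are group means. Pollen genes lay below wild type in all 3 libraries of 35S:DVL8 (-0.24, -0.55 and -0.16) and of both quintuple mutants, and the salicylate genes of 35S:DVL8 replicate 2 lay at 1.09.

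Compared directly, the overexpression lines differed in 6560 genes, 3761 higher and 2799 lower in dvl1-1D (57.3% higher; 44.8% after median-of-ratios scaling and 44.1% after quantile normalization). DVL1 (9.13) and AT1G27565 (4.07, adjusted p = 8.18e-12) were higher in dvl1-1D, as were AT5G45280 (23.5 ± 1.95 against 0.793 RPKM, 3.77, adjusted p = 4.81e-13), AT4G04223 (2.26) and AT3G06355 (29.2 against 5.47 RPKM, 2.21). DVL8 (-7.19) was lower, and so were PCC1 (17.5 against 47.9 RPKM, -1.44, adjusted p = 8.35e-05) and the snoRNA gene AT2G07605 (-1.42). PCR1, a cadmium resistance gene (0.889 against 18.4 ± 26.5 RPKM, -2.34 ± 0.66, adjusted p = 0.0153), and LURP1, a gene induced by a downy mildew (6.47 against 25.4 ± 17.58 RPKM, -1.62 ± 0.31, adjusted p = 0.00159), were lower too. Most of their level in 35S:DVL8 came from replicate 2 (49.0 and 45.2 RPKM), and without it the changes were -1.14 and -1.12; PCR1 did not pass in a fit of only the groups compared (0.0841) or with voom (0.13). In 44.1% of genes the libraries of both lines did not overlap, against 10% by chance.

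Between the quintuple mutants 3 genes differed, all lower in the dvl1 quintuple. AT3G30122 stood at 1.05 RPKM against 5.22 in the rtfl9 quintuple and 1.91 in wild type (-1.61 ± 0.14, adjusted p = 0.000231), AT4G04223 at 5.11 against 11.6 RPKM (-1.05, adjusted p = 0.00659), and AT3G29633 at 0.748 against 2.39 RPKM (-0.96, adjusted p = 0.00659). At an unadjusted p under 0.05 there were 887 genes, and 10% of genes had libraries that did not overlap, the share given by chance. After quantile normalization 1 gene was higher and 4 lower. AT3G29633 lost the call without dvl1 quintuple replicates 2 (0.0522) or 3 (0.0678) or rtfl9 quintuple replicate 2 (0.0648), and AT4G04223 without dvl1 quintuple replicate 3 (0.0678) or rtfl9 quintuple replicate 4 (0.0539). The count was 1 without dvl1 quintuple replicate 3 and 6 without its replicate 4.

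Both overexpression lines together were compared with both mutants to find genes that differ between them. Wild type is not part of this comparison, which therefore cannot show by itself that a gene follows DVL/RTFL dose. The cupin gene AT1G74820 (1.86, adjusted p = 1.99e-06), the lipid-transfer gene AT4G12530 (1.21), the peroxidase genes AT5G19880 (1.33) and AT4G11290 (1.23) and the very short AT5G23115 (1.51) were higher in the overexpression lines. The pseudogene AT5G35935 (-2.39), AT5G16090, a RAD23 repair-factor gene (-0.98 ± 0.08, adjusted p = 6.42e-06), the snoRNA gene AT2G43137 (-1.0), AT3G57960 (-0.91) and the kinase gene AT5G60080 (-0.88) were lower. AT5G16090, on chromosome 5 at 5255797 to 5257351, stood at 0.802 RPKM in dvl1-1D and 0.814 in 35S:DVL8, 1.33 in wild type, and 2.47 and 2.68 in the dvl1 and rtfl9 quintuples. AT5G35935 stood at 0.154 RPKM in dvl1-1D, 0.164 in 35S:DVL8, and 4.90 and 5.23 in the dvl1 and rtfl9 quintuples. Its wild-type level, 0.0137 RPKM, did not lie between those of the overexpression lines and the mutants. In all 6475 genes differed, 3000 higher and 3475 lower, but 229 did so for 35S:DVL8 against both mutants and 9336 for dvl1-1D against both. Of the 6475, 4176 were also called in the same direction in dvl1-1D minus wild type and 206 in 35S:DVL8 minus both mutants.

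The overexpression lines shared 11 called genes that moved the same way against wild type, 7 higher and 4 lower, where independent lists would share 2.01 and 2.25. They included HEI10, AT1G74820 (1.74 in dvl1-1D and 1.38 in 35S:DVL8), SWEET9 (0.97 and 0.63) and the transporter gene UMAMIT14 (-0.40 in both). Called in opposite directions were 4 genes, AT1G77940 (-0.19 and 0.47), AT2G43610 (0.26 and -0.53), FSD1 (-0.28 and 0.63) and AT5G02550 (0.27 and -0.36), which were chosen after their values were seen. Across genes, which are not independent replicates, the fold changes of both lines correlated at r = 0.24 (0.5 in simulations of unchanged groups with shared controls), with a covariance of 0.0113 against 0.0076 simulated. The simulated values are means without a spread, from groups that carry no effects. Differences from them were not tested, here or for the pairs below. Between comparisons that share no library, dvl1-1D minus wild type correlated with 35S:DVL8 minus the dvl1 and the rtfl9 quintuple at 0.19 and 0.17, but 35S:DVL8 minus wild type with dvl1-1D minus these mutants at -0.02 and -0.05, so the agreement depended on the control used. The number shared was 51 and 2 without 35S:DVL8 replicates 1 and 3, and 2, 2 and 3 without wild-type replicates 1, 2 and 3.

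All 6 genes called in the dvl1 quintuple were also called in the rtfl9 quintuple, in the same direction, where independent lists would share 0.0129 higher and 0.0182 lower genes. The correlation across genes was 0.76 against 0.46 simulated, and the covariance 0.0193 against 0.0067. With wild-type replicates 1, 2 and 3 left out in turn, 3, 4 and 3 genes were shared. Between overexpression lines and mutants, 38 genes were called in opposite directions and 31 in the same. HDA3, a histone deacetylase gene (-0.74 in dvl1-1D and 0.29 in the rtfl9 quintuple), the ribosomal protein genes RPSAb (-0.50 and 0.34), AT3G16780, AT5G09510 and AT3G47370, lower in dvl1-1D and higher in the rtfl9 quintuple, and SAG21, a senescence gene (0.45 and -0.61), were among the 38 and were chosen after their values were seen. For dvl1-1D and the rtfl9 quintuple alone, 29 genes were lower in the former and higher in the latter, where independent lists would give 9.12, and 9 the reverse, where they would give 30.8, without allowing for the shared wild type. In the same direction 19 were higher and 7 lower, against 10.9 and 25.8, so genes higher in the rtfl9 quintuple exceeded these numbers on both sides of dvl1-1D. Across genes this pair correlated at r = 0.06 against 0.46 simulated, with a covariance of 0.0028 against 0.0069. Without wild-type replicates 1, 2 and 3 the opposite genes numbered 2, 1 and 1, without rtfl9 quintuple replicates 1, 2 and 4 they numbered 2, 15 and 9, and without dvl1-1D replicate 1 and 35S:DVL8 replicates 2 and 3 they numbered 17, 66 and 23. With 3 wild-type libraries the controls could not be split with at least 2 libraries on each side, so part of the excess of genes shared in the same direction may come from the shared controls.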

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

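The tests of scaling, of an effect of equal size in both overexpression lines, of loss of DVL/RTFL function, of wild-type libraries that stand apart and of chance values shared through wild type were chosen only after their results were seen, as was the look at genes beside the switched genes.

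Lines of the same kind were tested directly against each other, and the results that differed between them are listed here. Between dvl1-1D and 35S:DVL8, 6560 genes differed. Between the dvl1 and rtfl9 quintuples only 3 did, and 0 in a fit of only those groups. DVL1 and DVL8, the genes that the overexpression lines raise, differ by construction of the lines. In dvl1-1D minus 35S:DVL8 the log2 fold changes were 9.13 for DVL1, 4.07 for AT1G27565, 3.77 for AT5G45280, 2.26 for AT4G04223 and 2.21 for AT3G06355. They were -7.19 for DVL8, -2.34 for PCR1, -1.62 for LURP1, -1.44 for PCC1 and -1.42 for AT2G07605, but -1.14 for PCR1 and -1.12 for LURP1 without 35S:DVL8 replicate 2. In the dvl1 minus the rtfl9 quintuple they were -1.61 for AT3G30122, -1.05 for AT4G04223 and -0.96 for AT3G29633.

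Of 20223 tested genes 6219 differed between dvl1-1D and wild type, against 28 for 35S:DVL8. Scaling of the libraries is argued against as the whole cause, because under median-of-ratios scaling and quantile normalization at least 2739 genes were called in each direction. An effect of the same size in both overexpression lines is argued against too: over the called genes, 35S:DVL8 minus both mutants had a slope of 0.09 on dvl1-1D minus wild type, and 0.07 to 0.12 with libraries left out in turn. Collection at another time of day stays open, since clock genes were among the largest changes and their projection correlated with that of the other called genes at r = 0.65 within the groups of 12 libraries (exact permutation p = 0.225 over 1296 permutations; Spearman's rho = 0.33, p = 0.431), but at 0.16 without replicates 4 and 1 of the rtfl9 quintuple. High DVL1 may also be the cause, which these libraries cannot separate from other differences of the line, since each genotype is a single line. Genes beside DVL1 differed too, among them AT5G16030 (log2 fold change 1.24), AT5G16010 (0.68) and NIK1 (0.54) higher and AT5G15980 (-0.31) lower. Whether these neighbours contributed to the other changes was not tested.

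Pollen genes were lower by camera in 35S:DVL8 and in the dvl1 and rtfl9 quintuples, but not with an estimated correlation (adjusted p = 0.355, 0.926 and 0.961), and 0, 0 and 1 of 15 members passed limma's test over all genes (9, 7 and 8 at an unadjusted p under 0.05). Fewer open flowers in the collected inflorescences is a candidate explanation: the 183 genes called lower in the rtfl9 quintuple outside the pollen list correlated with the list's mean within groups at a median of 0.83 over 9 libraries, against 0.02 in 1000 random gene sets, whose highest was 0.18. The correlation shows that these genes varied together with pollen genes, as genes active in pollen would for any cause. It cannot tell fewer open flowers from lower pollen gene expression in each flower, nor whether the plants or the harvest were the source. Loss of DVL/RTFL function stays open for the mutants, but the list's median was -0.31 in 35S:DVL8, where DVL8 is raised. Tapetum genes, which act in younger anthers, were higher by camera in both mutants (0.926 and 0.961 with an estimated correlation; 0 of 13 members called by limma, 4 and 6 at an unadjusted p under 0.05) and not called in 35S:DVL8, a difference that was not tested.

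In 6 genes at least 3 of the 4 lines differed from wild type in the same direction: HEI10, AT2G05705, AT2G13550, RLP18, AT3G06355 and AT3G29644. Wild-type libraries that stand apart from all lines are argued against as the whole cause for 3 of them (AT2G13550, AT3G06355 and AT3G29644), which also differed among 35S:DVL8 and the mutants. The rule against chance values shared through wild type, a difference among those lines or from wild type after Bonferroni adjustment, was met by 5: these 3, HEI10 and AT2G05705. A difference among the lines does not bear on chance in wild type. Chance is therefore argued against as the whole cause only for AT3G29644, HEI10 and AT2G05705. There the mean of the 4 lines differed from wild type with a Bonferroni p over all genes of 6.22e-06, 3e-04 and 0.000627. With a library left out, where tested, it was at most 0.000242, 0.0114 and 0.0023. With a pseudocount of 0.1 it was 0.293 for AT2G05705. For RLP18 chance stays open (0.159), as it does for AT2G13550 and AT3G06355 (0.0888 and 0.0208, up to 1 and 0.474 with a library left out). For HEI10, AT2G05705 and RLP18 wild-type libraries that stand apart cannot be told apart from an effect of the lines, since the smallest adjusted p among those lines was 0.389. A background variant shared by the lines was not tested.

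The libraries were also split in other ways. For the 6475 genes between both overexpression lines and both mutants, 1 of 100 splits, the real one, gave as many, and the highest other gave 1564. The other splits shuffled single libraries across the lines, which widens the spread within groups. Their lower counts therefore cannot tell whether pairing the lines this way matters. Other pairings of whole lines, which were not among those splits, gave 3566 genes (dvl1-1D and the dvl1 quintuple against the rest) and 2861 (dvl1-1D and the rtfl9 quintuple against the rest), so many genes differed however the lines were paired. For the other comparisons the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real gene counts were 6219, 28, 6, 249, 6560 and 3, each reached by 1 split, and the highest of the other splits gave 0 genes, or 1 in dvl1-1D against 35S:DVL8. For gene lists the real counts were 1 in dvl1-1D, 7 in 35S:DVL8 and 3 in each mutant, and the highest other counts 5, 8, 6 and 6, with 9, 2, 6 and 6 of the 10 splits reaching the real count.

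Some genes were switched nearly on or off in 1 or 2 lines, and these were chosen after their values were seen. AT5G45280 fell by 3.60 on the log2 scale in 35S:DVL8, where its 7 tested neighbours within 20 kb had adjusted p of at least 0.322 and absolute log2 fold changes of at most 0.3. AT5G35935 rose in both quintuple mutants, where its single tested neighbour changed by 0.02 and 0.06. AT1G27565 rose by 4.1 in dvl1-1D, where 1 of 5 tested neighbours, AT1G27540, was called (0.22, adjusted p = 0.0409).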

How the results depend on the processing

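The fits with voom and without the pair of libraries farthest from their groups were chosen after seeing the data; all other alternatives were planned. No named gene that had passed the test reversed under any of them. Of the values of named genes in dvl1-1D minus wild type, 949 of 964 kept direction and side of the threshold, and 478 of 519 with libraries left out in turn. The corresponding numbers were 133 of 166 and 44 of 87 for 35S:DVL8, 58 of 62 and 27 of 33 for the dvl1 quintuple, 162 of 181 and 51 of 99 for the rtfl9 quintuple, 105 of 107 and 51 of 51 between the overexpression lines, 24 of 31 and 13 of 18 between the mutants, and 134 of 136 and 150 of 150 between overexpression lines and mutants. A pseudocount of 0.1 and robust moderation moved no count by over 1.5 times. The planned count model for raw counts was not run, because the deposited unit was RPKM. RTFL11, with 21 to 37 reads per group, lay under the RPKM filter. Depth limited the fold of DVL1, which was computed against a floor of 3 reads over the wild-type libraries.

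Without a filter the counts were 2 lists in dvl1-1D, 12 genes in the dvl1 quintuple, 57 in the rtfl9 quintuple (30 higher, 27 lower), 11 shared by both mutants and 13 opposite in overexpression lines and mutants. With RPKM of at least 5 they were 2 lists in dvl1-1D, 2 genes in the dvl1 quintuple, 1 between the mutants, 5 shared by both overexpression lines and 2 by both mutants, with fewer genes tested. Median-of-ratios scaling and quantile normalization each called 2 lists in dvl1-1D, and the latter 5 genes between the mutants. Under quantile normalization the uncalled log2 fold change of DVL8 was 0.02 in both mutants (adjusted p = 0.982 in the dvl1 and 0.959 in the rtfl9 quintuple), in place of -0.04 and -0.06. Array weights gave 306 genes in 35S:DVL8 (74 higher, 232 lower), 18 genes and 6 lists in the dvl1 quintuple, 668 genes in the rtfl9 quintuple, 5 between the mutants, 78 shared by the overexpression lines, 17 by the mutants and 197 opposite. A fit of only the groups compared gave 161 genes (14 higher, 147 lower) and 5 lists in the dvl1 quintuple, 0 between the mutants (887 at an unadjusted p under 0.05 with all groups in the limma fit) and 104 shared by the mutants. With an estimated correlation 0 lists were called by camera in each of the 4 lines. With a log2 fold change of at least 1 the counts were 138, 6, 3 and 12 against wild type, 131 between the overexpression lines, 2 between the mutants and 19 between overexpression lines and mutants. Apart from the thresholds, which keep fewer genes by construction, the cause was not tested.

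The replicate numbers showed no general pairing of the samples: of 23 pairs with the same number, 2 had a correlation over 0.1 (range -0.26 to 0.38), and 2 libraries correlated best with their own number. The highest value, 0.38, was that of replicate 4 of the dvl1 and rtfl9 quintuples, the single pair with that number. A factor shared by these libraries is therefore not excluded. With the replicate block the counts were 13 genes in 35S:DVL8, 6 lists in the dvl1 quintuple, 9 genes (7 higher, 2 lower) and 6 lists in the rtfl9 quintuple, 1 gene between the mutants, 5 shared by the overexpression lines, 3 by the mutants and 2 opposite. Voom gave 241 genes in 35S:DVL8 (48 higher, 193 lower), 48 shared by the overexpression lines and 64 opposite. Without 35S:DVL8 replicate 2 and rtfl9 quintuple replicate 4 there were 47 genes and 1 list in 35S:DVL8, 152 genes in the dvl1 quintuple (11 higher, 141 lower), 1 list in the rtfl9 quintuple, 1 gene between the mutants, 22 shared by the overexpression lines, 138 by the mutants and 63 opposite. The cause was not tested.

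With single libraries left out, the counts of genes ranged from 4775 to 5223 in dvl1-1D, 4 to 287 in 35S:DVL8, 4 to 6 in the dvl1 quintuple, 7 to 79 in the rtfl9 quintuple, 5130 to 5662 between the overexpression lines, 1 to 6 between the mutants and 5094 to 6283 between overexpression lines and mutants. Lists ranged from 1 to 1, 1 to 9, 2 to 7 and 2 to 4 in the 4 lines. Shared genes ranged from 2 to 51 in the overexpression lines and 3 to 6 in the mutants, opposite genes from 1 to 66, and called neighbours of DVL1 from 5 to 6.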

Other observations

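The functional terms and the shares of non-coding genes described here were chosen only after the data were seen.

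Among the genes called in dvl1-1D, those annotated to translation, ribosome biogenesis, nucleosome assembly and DNA replication were mostly lower, and those of signalling mostly higher. Of 360 tested genes annotated to translation, 181 were called lower and 8 higher than wild type, a split that differed from that of all called genes (Fisher's exact test, adjusted p = 3.29e-50 over 118 terms). Among 99 genes of ribosome biogenesis 49 were lower (adjusted p = 6.22e-16), as were 25 of 50 genes of nucleosome assembly (6.7e-08), many of them similar histone copies whose reads are uncertain, and 14 of 39 genes of DNA replication (0.000178). Protein phosphorylation genes were mostly higher, 176 against 33 of 618 (1.2e-18), and so were those of signal transduction, 55 against 10 of 194 (4.62e-06), the defense response, 53 against 13 of 200 (0.000178), and the response to auxin, 18 against 3 of 53 (0.0143). These directions were the same after median-of-ratios scaling and quantile normalization, with 210 and 162 translation genes lower. Genes are not independent replicates, so these p-values describe the split within the called genes of these libraries.

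Non-coding genes and pseudogenes made up 3.4% of the tested genes. They were 17.9% of the 28 genes called in 35S:DVL8 (Fisher's exact test, adjusted p = 0.00316 over 7 comparisons), 66.7% of the 6 called in the dvl1 quintuple (3.24e-05), 4% of those in the rtfl9 quintuple (0.594) and 2.4% of those in dvl1-1D (2.36e-07). The test treats genes as independent, which they are not. AT2G05705 and AT3G29644 count in both 35S:DVL8 and the dvl1 quintuple, against the same wild-type libraries. DVL20, a family member outside the list, was higher in dvl1-1D (0.94 ± 0.13, adjusted p = 0.000136).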
